A study of Homo sapiens with 16 samples.

How the data were processed

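RNA was measured in Mel1, an established human embryonic stem cell line, and in cells derived from it at 3 later stages of an in vitro differentiation to pancreas. The 4 groups, taken from the sample titles, were undifferentiated cells (ESC), definitive endoderm (DE), pancreatic endoderm (PE) and pancreatic progenitors (PP), with 4 libraries each and 16 in all. Per the labels' protocols, total RNA with a RIN above 8 was enriched for polyadenylated RNA, and the libraries were made with a TruSeq stranded mRNA kit, which keeps the strand of the RNA. Nothing in the labels says that the 4 libraries of a stage came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

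Per the submitters' processing notes, the build was hg38 and the tools included STAR, SAMtools, deepTools and DESeq2 1.22.1, with no roles given. The program that counted the reads, its strand setting and the annotation release are not given in the sources used here. The authors deposited FPKM values, which divide each gene's count by its length and its library's total. The authors also deposited values after DESeq2's variance stabilising transformation (VST), which are on a log2 scale for high counts, are compressed for low counts and level off at 5.40 for a count of 0. Both tables held 60675 rows with Ensembl identifiers. Of these rows, 3073 had no FPKM value, and these held 1.11% of the counts and were left out of the tests. GENCODE release 29 matched 57055 rows (94.0%). In 94.7% of 29585 rows, the length implied by FPKM lay within 1% of the summed exon length of that release. Coordinates and strands were taken from it. Symbols came from a separate list of gene names where that held one, and otherwise from release 29.

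Whole counts were recovered from the VST values, because each library maps a whole count to a single value. Each recovered count lay within 0.01 of a whole number, and the same step recovered 100% of simulated counts. The total per library ran from 1468773 to 1745939, and 16617 to 17948 rows per library had a count. At this depth a low row rests on few reads. For a stage with no count in a row, the FPKM that 3 counts over its 4 libraries would give is printed as a floor. Floors cover counting error only, because the reads carry no molecular identifiers. The 24 pairs of libraries within a stage were compared by a chi-square test on rows with at least 20 counts, and each pair differed by more than counting noise (chi-square per degree of freedom 1.36 to 13.4), so no library was taken as a second copy of another. This does not show that they are independent. Replicates 1 and 2, and 3 and 4, were closer than the other pairs in ESC (1.48 and 1.62, against 4.05 to 5.21), PE (1.93 and 2.19, against 2.48 to 5.19) and PP (3.14 and 4.97, against 9.58 to 13.4), and replicates 1 and 2 in DE (1.36, against 4.08 to 4.81 for all others). The p-values below treat the 4 libraries of a stage as separate, and are too small if such pairs share a culture.

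The values are described row by row, because most counts lay in rows that overlap exons of a gene on the other strand. A gene's own row is the row of its identifier. A row was paired with an opposite gene where bedtools 2.31.1 found at least 100 bp of exon overlap on the other strand and at least 80% of all such overlap came from that gene. Of the 12325 tested rows, 5232 had such a partner. Rows named for their size of change are written at first with that gene, such as TCF19 opposite POU5F1, while the own rows of markers and list members are mostly written by their symbol alone. The pairing was chosen after the data were seen.

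Rows with a mean FPKM of at least 1 in at least 1 stage were tested, 12325 in all, and they held 97.7% of the counts. Differences between stages were tested on the VST values with limma 3.58.1 in R 4.3.3, in a single model of the 4 stages with 12 residual degrees of freedom, a variance trend and robust moderation. P-values carried Benjamini-Hochberg (BH) adjustment. A row was called when its adjusted p was under 0.05 and its difference at least 1 on the VST scale, which asks more of low counts than of high ones. Every adjusted p below comes from limma, or from camera for a gene list. Means and SDs are of FPKM over the 4 libraries of a stage. Data were simulated over 12325 rows with the row means and spread of all 16 libraries, and changes were placed in DE. The changed rows were drawn only from rows above a minimum mean count, so recovery in lower rows was not measured. For DE against ESC, limma on VST values recovered 4.5% of changes of 2-fold, 83.6% of 4-fold and 93.9% of 8-fold, with 0 false calls. The voom method recovered 43.3%, 97.0% and 100%, with 9 false calls. A 2-fold change lies at or under the minimum difference of 1, so its recovery reflects that minimum more than the spread between libraries. In the same simulation camera called the 1 changed list and 0 of 30 unchanged lists.

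The comparisons (DE with ESC, PE with DE, PP with PE, and PP with ESC), the test, the gene lists and the rule for naming genes were set before the data were examined. The rule took, per comparison, the 5 called rows with a symbol that rose most and the 5 that fell most, with at least 5 FPKM in the higher stage and no overlap between libraries. It also took up to 3 called members of 4 focus lists and 2 to 4 of other lists described, 16 fixed markers, and 5 rows per stage for those that peaked there. Rows named by a clone identifier, such as AC091588.3, and any others outside the rule were chosen after their values were seen. Results of some genes that the rule takes are not reported here. Lists were read through the members' own rows. The 33 lists covered pluripotency, primitive streak, definitive endoderm, gut tube and foregut, pancreatic progenitor, endocrine, acinar, ductal, hepatic, intestinal and gastric, mesenchyme, neural and neural crest, endothelial and blood, trophoblast and amnion, targets of WNT, NODAL and activin, BMP and retinoic acid, Hedgehog, Notch, anterior and posterior HOX, proliferation, glycolysis, hypoxia, cholesterol synthesis, the secretory and unfolded protein response, epithelial junctions, mesenchymal transition, monogenic diabetes, polycomb and DNA methylation, mitochondrial transcripts and reference genes. The 24 lists with at least 5 tested members were tested against the other rows with camera at a preset correlation of 0.01, and BH adjustment covered the 96 tests.

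The alternatives were the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), no FPKM filter (30210 rows) or a minimum of 5 (5971 rows), quantile, median and reference gene scaling, only the stages compared, no variance trend, no minimum difference, treat against a difference of 1, each library left out in turn, and an estimated correlation or fry for lists. Added after the data were seen were voom on the recovered counts, the rows with or without opposite overlap alone, the PP libraries in pairs, replicates 1 and 2 against 3 and 4 as a batch term, libraries 1 and 2, and 3 and 4, of each stage averaged to 1 value each, and lists read through opposite rows. Reference gene scaling set each library to the mean VST value of the reference genes' own tested rows. Those rows have low values, so it is not a scaling by abundant transcripts. Other software was numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.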

Results

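The 16 libraries held between 1468773 and 1745939 counted reads, 4 libraries at each of 4 stages from undifferentiated Mel1 cells (ESC) through definitive endoderm (DE) and pancreatic endoderm (PE) to pancreatic progenitors (PP). Values below are FPKM, mean ± SD over the n = 4 libraries of a stage, and differences are on the VST scale.

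The counts lay mainly in rows annotated on the strand opposite to well-known abundant genes. AC006064.4 (chromosome 12, 6537794 to 6538370, minus strand) overlaps 422 bp of exon of GAPDH, a glycolytic enzyme gene, and averaged 72300 FPKM over the stages. Likewise AL662797.1 opposite TUBB, a tubulin gene, averaged 22600 FPKM, and AL138963.3 opposite TPT1 averaged 23300 FPKM. MT-ND6, the mitochondrial coding gene on the light strand, stood at 41800 FPKM, whereas the 12 coding genes of the heavy strand had a median of 791 FPKM and a highest value of 4470 FPKM. The own rows of 18 commonly used reference genes had a median of 0.769 FPKM, with a range of 0.063 to 8.70. Rows with exon overlap on the other strand were 21.7% of annotated rows and held 89.6% of the counts (88.3% to 91.3% per library). For 115 coding genes whose opposite non-coding row held at least 20000 counts, the read density of the own row had a median of 0.0781% of that of the opposite row (quartiles 0.0384% and 0.250%). The own density is the count over the row's exon length. The opposite density is that row's whole count over the overlapping exon length alone, so opposite reads outside the overlap lower the ratio. Values below are therefore given as values of a row, in SOX17, PDX1 and the other markers as in rows opposite a known gene, and not as levels of a gene's mRNA.

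**Figure D1:**
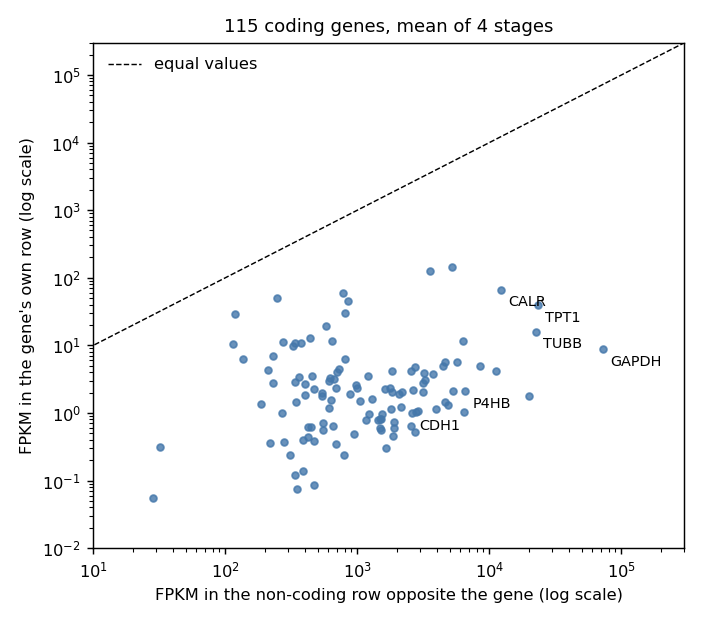
Each point is 1 of 115 protein-coding genes, with the FPKM of the non-coding row opposite it on the horizontal axis and the FPKM of its own row on the vertical axis, both on log scales and averaged over the 4 stages. The own rows lie far below the opposite rows. The median density ratio of 0.0781% in the text divides opposite counts by the overlap length, so it is not the ratio of the FPKM values plotted.

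The libraries grouped by stage. The first principal component of the VST values held 53.8% of the variance and the second 26.2%. Correlations between libraries of a stage ran from 0.986 to 0.992 in ESC, DE and PE and from 0.977 to 0.991 in PP. Between PE and PP they ran from 0.966 to 0.973, and between ESC and PP from 0.883 to 0.895. The PP libraries differed among themselves on the fourth component, which held 2.8% of the variance, with scores of -10.74 and -11.58 for replicates 1 and 2 and of 11.91 and 13.72 for replicates 3 and 4.

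**Figure D2:**
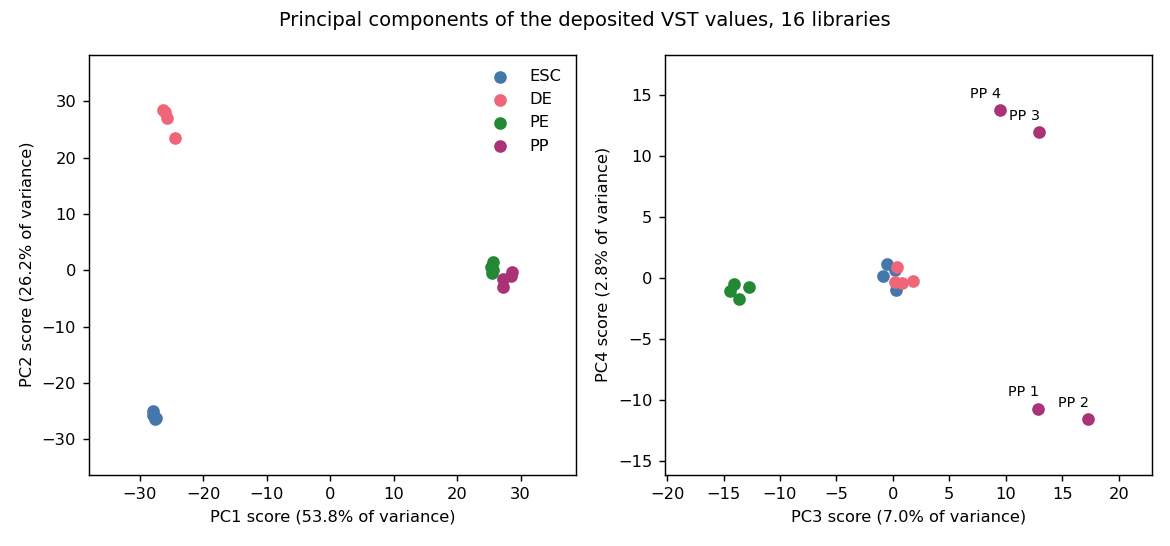
Scores of the 16 libraries on principal components 1 and 2 (left) and 3 and 4 (right) of the VST values, coloured by stage, with the share of variance on each axis. ESC and DE separate from each other and from the later stages on components 1 and 2. PE and PP lie close together there and part on component 3. PP replicates 1 and 2 lie apart from 3 and 4 on component 4.

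The markers fixed in advance had low values in their own rows, and those of several endoderm and pancreas regulators nonetheless differed between stages. SOX17, a transcription factor of definitive endoderm (chromosome 8, 54457935 to 54460888, plus strand), had no count in ESC, where the floor is 0.202 FPKM, and had 22.4 ± 2.95 in DE, 0.570 ± 0.538 in PE and 0.187 ± 0.236 in PP. GATA6, an endoderm transcription factor, had no count in ESC (floor 0.120 FPKM), 3.97 ± 0.998 in DE, 3.64 ± 1.31 in PE and 1.74 ± 0.546 in PP. SOX2, a pluripotency factor, was at 14.3 ± 1.48 FPKM in ESC and at 0.435 ± 0.542, 1.34 ± 0.130 and 0.578 ± 0.708 in DE, PE and PP. PDX1, a regulator of pancreas formation (chromosome 13, 27920020 to 27926231, plus strand), had no count in ESC or DE (floors 0.189 and 0.192 FPKM), 2.38 ± 1.13 FPKM in PE and 4.15 ± 0.837 in PP. SOX9, a pancreatic progenitor and duct factor, was at 0.159 ± 0.184 FPKM in ESC, had no count in DE (floor 0.122), and was at 1.58 ± 1.11 in PE and 6.97 ± 1.49 in PP. NKX6-1, a beta cell and progenitor factor, was at 0.0509 ± 0.102 in ESC, had no count in DE (floor 0.156), and was at 0.0932 ± 0.108 in PE and 4.21 ± 2.68 in PP, where it rested on 10 to 42 counts per library.

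Of these, limma called SOX17 in DE against ESC (1.93 ± 0.09 SE, adjusted p = 1.31e-15) and in PE against DE (-1.67, adjusted p = 2.6e-14), GATA6 in DE against ESC (1.11, adjusted p = 4.98e-11), SOX2 in DE against ESC (-1.40, adjusted p = 4.79e-12) and in PP against ESC (-1.37, adjusted p = 5.31e-12), and SOX9 in PP against ESC (1.24, adjusted p = 1.09e-10). Others missed the minimum difference with a small adjusted p. PDX1 differed by 0.64 in PE against DE (limma, adjusted p = 1.37e-07) and by 0.88 in PP against ESC (adjusted p = 2.83e-10), and NKX6-1 by 0.85 in PP against PE (adjusted p = 8.75e-07). Both were called with log2(FPKM + 1) and with voom. PTF1A, a regulator of pancreas and acinar cells, had counts in PP alone, at 1.05 ± 0.582 FPKM, with floors of 0.290, 0.295 and 0.269 in ESC, DE and PE. NEUROG3, the endocrine progenitor factor, was at 0.113 ± 0.227 in ESC, had no count in DE or PE and was at 2.13 ± 1.25 in PP. Against PE, PTF1A differed by 0.34 (limma, adjusted p = 9e-05) and NEUROG3 by 0.45 (adjusted p = 5.8e-05).

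FOXA2, an endoderm transcription factor, had no count in ESC (floor 0.182) and was at 1.61 ± 0.604 FPKM in DE, 1.96 ± 0.430 in PE and 1.81 ± 0.368 in PP. ONECUT1, a liver and pancreas factor, was at 1.15 ± 0.226, 9.30 ± 4.65, 1.63 ± 0.693 and 1.06 ± 0.527 FPKM in ESC, DE, PE and PP. Its difference in DE against ESC was just under 1 (limma, adjusted p = 7.81e-08) and reached 1.12 without DE replicate 1. CXCR4, a chemokine receptor used as an endoderm surface marker, had counts in DE (1.16 ± 0.290) and PP (0.196 ± 0.251) and none in ESC (floor 0.213) or PE. POU5F1, a core pluripotency factor, was at 3.94 ± 0.537, 1.46 ± 1.29, 0.200 ± 0.164 and 0.708 ± 0.411 FPKM, and its difference of -0.57 in PP against ESC was under the minimum. HNF4A and NANOG stayed under 1 FPKM at each stage and were not tested, with highest means of 0.760 ± 0.196 in PE and 0.146 ± 0.220 in ESC. INS, the insulin gene, had no count in any of the 16 libraries, and the floor in PP is 0.566 FPKM. For rows named below as having no count at a stage, the floor ran from 0.0439 FPKM (MEIS1 in DE) to 0.360 FPKM (CER1 in PE).

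**Figure D3:**
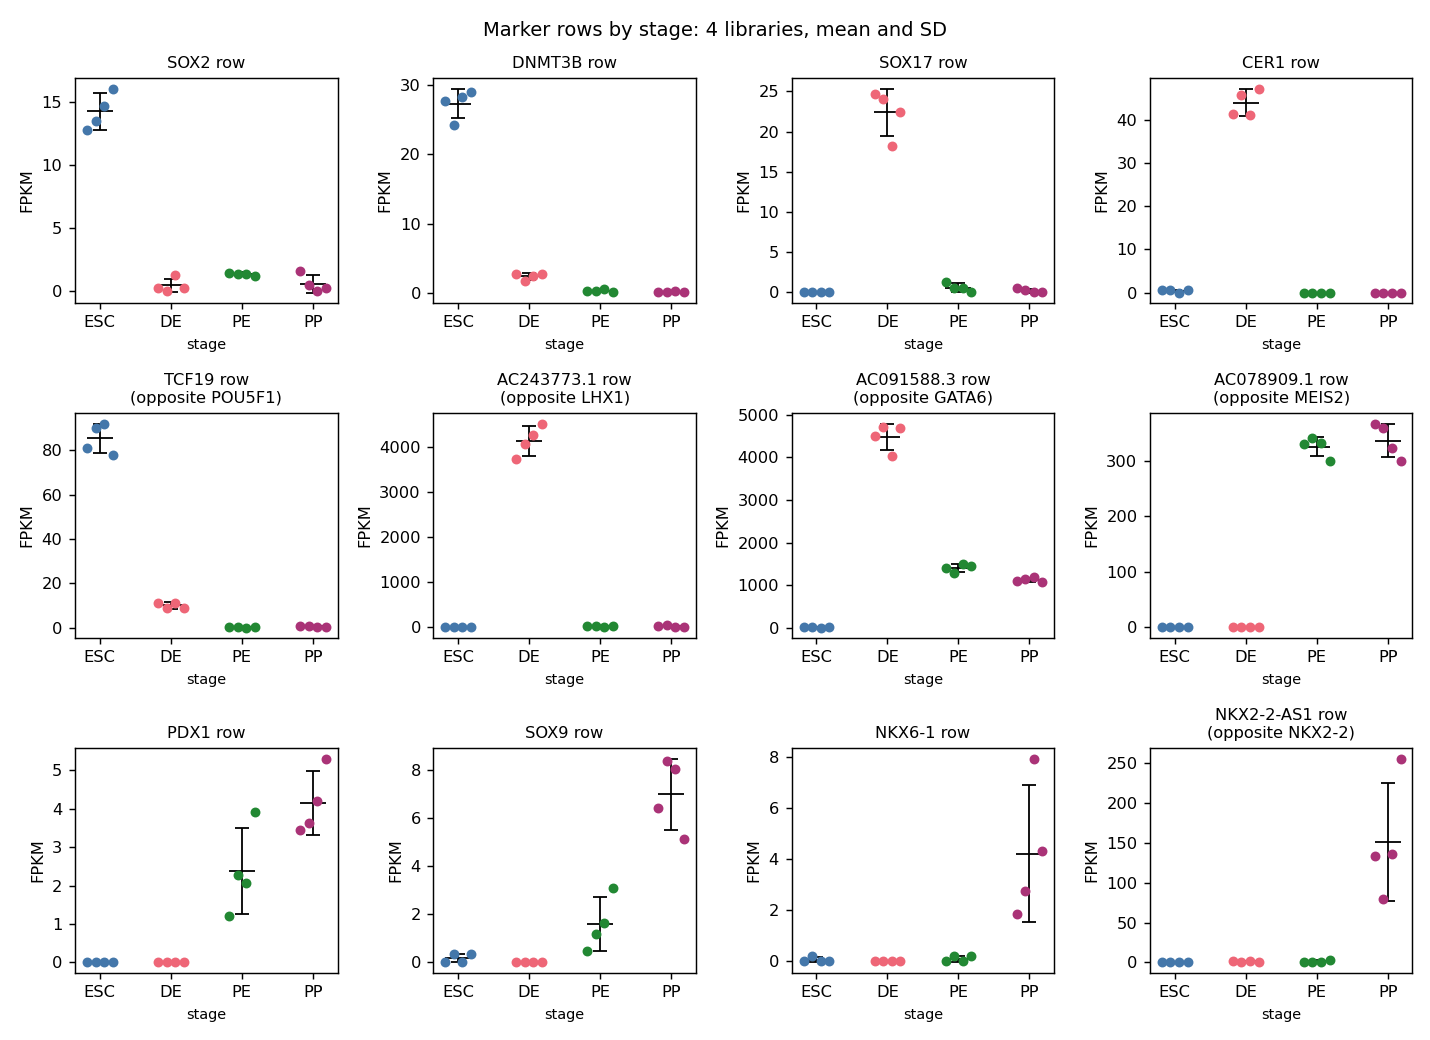
FPKM by stage for 12 rows, with 1 point per library and the mean and SD of 4 libraries as bars, for genes' own rows and for rows named with the gene opposite them. The row AC243773.1 opposite LHX1 stands at 4130 ± 332 in DE, and the SOX17 row at 22.4 ± 2.95.

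DE was compared with ESC to ask which transcripts change when pluripotent cells form definitive endoderm, the layer that gives rise to gut, liver and pancreas. Own rows of 6 of 8 tested NODAL and activin targets and of 7 of 15 definitive endoderm genes rose. CER1, a secreted NODAL and BMP antagonist (chromosome 9, 14719724 to 14722717, minus strand), rose from 0.390 ± 0.260 to 44.0 ± 3.13 FPKM (limma, adjusted p = 4.93e-17), and SOX17 rose from no count to 22.4 ± 2.95. Of 20 tested pluripotency genes 2 fell and 1 rose. One that fell was DNMT3B, a DNA methyltransferase abundant in pluripotent cells (chromosome 20, 32762385 to 32809356, plus strand), from 27.3 ± 2.14 to 2.45 ± 0.513 FPKM (limma, adjusted p = 5.47e-17). Among rows opposite known genes, AC091588.3 opposite GATA6 (chromosome 18, 22200619 to 22205229, minus strand, 321 bp of overlap) rose from 14.3 ± 3.13 to 4480 ± 315 FPKM, and TCF19, a row that overlaps 248 bp of POU5F1 exon, fell from 85.4 ± 6.72 to 10 ± 1.43.

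In the definitive endoderm list, 7 of 15 tested members rose and 0 fell, with 7 also when adjusted over the list alone (camera, adjusted p = 7.76e-10). Beside SOX17, CER1 and GATA6 these were LEFTY1 and LEFTY2, which are NODAL inhibitors, the growth factor FGF17 (0.0478 to 12.5 ± 2.50 FPKM, limma, adjusted p = 3.94e-15) and GATA4 (no count to 7.85 ± 2.05, adjusted p = 9.53e-05). In the primitive streak list 3 of 6 rose, 3 adjusted over the list alone (camera, adjusted p = 0.000205). They were FGF17, EOMES, a T-box factor needed for endoderm (no count to 4.33 ± 1.21), and LHX1 (no count to 11.1 ± 0.956, limma, adjusted p = 4.08e-18). Of 8 tested NODAL and activin targets 6 rose, 6 adjusted over the list alone (camera, adjusted p = 4.33e-08). In the pluripotency list 2 of 20 fell (DNMT3B and SOX2) and 1 rose, with the same counts adjusted over the list alone (camera, adjusted p = 0.00022). The member that rose was FOXH1, a transcription factor that carries NODAL signals, from 89.2 ± 12.6 to 346 ± 30.1 FPKM in a row opposite KIFC2. The row opposite FOXH1 was not called in this comparison. CDH2, which codes for N-cadherin, was the 1 called member of 7 in the mesenchymal transition list, 1 adjusted over the list alone (camera, adjusted p = 0.00433), and went from 0.320 to 6.46 ± 1.03 FPKM. DNMT3B was the 1 of 6 called in the polycomb and DNA methylation list, 1 adjusted over the list alone (camera, adjusted p = 0.00435), and that list's adjusted p = 0.0627 with an estimated correlation. The gut tube and foregut list had 0 of 14 called, 0 adjusted over the list alone (camera, adjusted p = 0.532), and 5 of its members were higher and 1 lower by the limma adjusted p without the minimum difference.

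The rows with the largest rises under the naming rule included CCNYL1 opposite AC096772.1 (12.8 ± 2.38 to 496 ± 30.8 FPKM), TTN-AS1 opposite TTN (0.910 to 44.8 ± 3.69), LYRM2 opposite ANKRD6 (5.85 to 125 ± 6.81) and HAS2-AS1 opposite HAS2, a hyaluronan synthase gene (20.1 ± 5.30 to 486 ± 7.38). The largest falls were in MMP24OS opposite MMP24 (138 ± 13.6 to 2.42), NUDT6 opposite FGF2, a growth factor that sustains pluripotent cells (131 ± 13.4 to 4.48 ± 1.42), TLDC2 opposite SAMHD1 (162 ± 15.9 to 1.91 ± 1.64), GNAS-AS1 (382 ± 47.9 to 26.6 ± 9.05) and PCSK7 opposite AP000892.3 (97.7 to 8.29). Among rows chosen after their values were seen, AC243773.1 opposite LHX1 rose from 6.09 ± 1.15 to 4130 ± 332, AC022532.1 opposite NODAL from 349 ± 33.0 to 2090 ± 116, AC110015.1 opposite CDH2 from 151 ± 24.5 to 2550 ± 64.3 and AC078860.1 opposite LGR5 from 3.59 to 247 ± 26.1. Z99774.1 opposite MIAT fell from 855 ± 138 to 3.58 ± 1.41, THY1-AS1 opposite THY1 from 4040 ± 114 to 424 ± 74.6, and AC099314.1 opposite CDH1, the E-cadherin gene, from 3150 ± 97.4 to 669 ± 75.5.

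Of 12325 rows, limma called 521, with 306 higher and 215 lower in DE, and 407 of them overlap exons on the other strand. The count was 269 with treat, 2260 with log2(FPKM + 1) and 3071 with voom.

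PE was compared with DE to ask what follows once endoderm cells move toward the pancreas. The row of IGF2, an insulin-like growth factor (chromosome 11, 2129112 to 2149603, minus strand), rose from 8.36 ± 3.38 to 2160 ± 438 FPKM (6.97 ± 0.21 SE, limma, adjusted p = 1.22e-12). The row AC078909.1 opposite MEIS2, a homeobox factor (chromosome 15, 37099339 to 37100173, plus strand, 431 bp of overlap), rose from 0.696 ± 0.806 to 325 ± 17.3. Of the 8 NODAL and activin targets 6 fell, with CER1 going from 44.0 ± 3.13 FPKM to no count. LARP7, whose row (chromosome 4, 112636964 to 112657592, plus strand) overlaps 302 bp of exon of MIR302CHG, the host gene of a microRNA cluster of pluripotent cells, fell from 4270 ± 379 to 14 ± 7.41 FPKM (adjusted p = 1.58e-14).

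In the definitive endoderm list 5 of 15 fell, 5 adjusted over the list alone (camera, adjusted p = 3.88e-07), in the primitive streak list 3 of 6, 3 adjusted over the list alone (adjusted p = 1.48e-05), and among NODAL and activin targets 6 of 8, 6 adjusted over the list alone (adjusted p = 3.43e-09). EOMES, a member of the last pair of lists, fell by 0.99, under the minimum, when libraries were scaled to the reference gene mean. In the pluripotency list 2 of 20 fell, 2 adjusted over the list alone (camera, adjusted p = 0.00589), namely FOXH1 (346 ± 30.1 to 106 FPKM) and L1TD1, an RNA-binding protein gene of stem cells (13.2 ± 2.27 to 0.189). In the gut tube and foregut list 2 of 14 rose, 2 adjusted over the list alone (camera, adjusted p = 0.00381), namely the homeobox genes MEIS1 (no count to 3.99 ± 0.819) and MEIS2 (0.0142 to 2.69 ± 0.842, limma, adjusted p = 2.63e-11). FGB, a fibrinogen chain gene of the liver, was the 1 called of 8 hepatic members, 1 adjusted over the list alone (camera, adjusted p = 0.000178), and went from no count to 14.7 ± 1.71 FPKM.

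Among retinoic acid targets 6 of 17 rose, 6 adjusted over the list alone (camera, adjusted p = 0.00137), and adjusted p = 0.25 with an estimated correlation. They included MEIS1, MEIS2, the nuclear receptor genes NR2F1 and NR2F2 (no count to 5.39 ± 1.13, limma, adjusted p = 9.11e-14) and HOXA2. In the anterior HOX list 3 of 9 rose, 3 adjusted over the list alone (camera, adjusted p = 0.0114), with adjusted p = 0.51 with an estimated correlation and 0.056 with log2(FPKM + 1). These genes pattern the anterior body axis, and those that rose included HOXA2 (no count to 16.1 ± 3.29 FPKM, limma, adjusted p = 0.000838) and HOXB3 opposite HOXB-AS1 (0.110 to 7.82 ± 1.84, adjusted p = 0.000515). With libraries 1 and 2, and 3 and 4, of each stage averaged, neither was called (limma, adjusted p = 0.08 and 0.0608). DLL4, a Notch ligand, was the 1 of 7 called in the Notch list, 1 adjusted over the list alone (camera, adjusted p = 0.0221), with adjusted p = 0.177 with an estimated correlation and 0.0636 with log2(FPKM + 1). CALR, a chaperone of the endoplasmic reticulum, was the 1 of 11 called, as a fall, in the secretory and unfolded protein response list, 1 adjusted over the list alone (camera, adjusted p = 0.0114), with adjusted p = 0.124 with an estimated correlation. Its own row went from 107 ± 7.30 to 48.4 ± 5.48 FPKM, and the fall was 0.94 with reference gene scaling, under the minimum. Mitochondrial transcripts had 0 of 13 called, 0 adjusted over the list alone (camera, adjusted p = 0.00435), with adjusted p = 0.452 with an estimated correlation, and 8 were lower by the limma adjusted p without the minimum difference.

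The largest rises under the naming rule, beside IGF2, were in NRAP opposite HABP2, a serine protease gene of the liver (0.701 to 303 ± 20.1 FPKM, limma, adjusted p = 2.81e-22), SLC46A1 opposite SARM1 (9.73 to 280 ± 5.75), APOA1-AS opposite APOA1, an apolipoprotein gene of liver and gut (37.3 ± 6.39 to 1770 ± 88.7), and CCDC154 opposite AL032819.2 (0.645 to 168 ± 16.5). Beside LARP7 the largest falls included MAGEB17 opposite AC078993.1 (2120 ± 49.4 to 3.78), HAS2-AS1 opposite HAS2 and PPP6R3 opposite AP003096.1 (63.1 ± 2.73 to 0.193). Of rows chosen after their values were seen, AC008738.3 opposite CEBPA, a liver transcription factor gene, rose from 18.9 ± 3.47 to 2040 ± 106, NR2F1-AS1 opposite NR2F1 from no count to 37.7 ± 9.59 and AC113386.1 opposite CDH6 from 2.15 ± 2.63 to 943 ± 139. AC243773.1 opposite LHX1 fell from 4130 ± 332 to 27.7 ± 6.45, AC022532.1 opposite NODAL from 2090 ± 116 to 1.53 and AC126696.2 opposite the amino acid transporter gene SLC7A5 from 4820 ± 994 to 126 ± 27.3, while AC099314.1 opposite CDH1 rose from 669 ± 75.5 to 2290 ± 70.4.

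Of 12325 rows limma called 638, with 249 higher and 389 lower in PE, and 39.0% were higher. With libraries scaled to the mean of the reference genes' own rows, which shifted the median difference by 0.123, 329 were higher and 305 lower (51.9% higher). The majority turned to higher with log2(FPKM + 1), with 1513 higher and 1186 lower, and with voom, with 2117 higher and 1558 lower. The majority stayed lower with treat, which called 341, with 118 higher and 223 lower. In the rows without opposite overlap, a choice made after the data were seen, 34 were higher and 113 lower (23.1% higher).

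PP was compared with PE to ask what separates pancreatic progenitors from the stage before. NKX2-2-AS1 opposite NKX2-2, an endocrine and progenitor transcription factor (chromosome 20, 21511447 to 21512309, plus strand, 638 bp of overlap), rose from 1.14 ± 1.14 to 151 ± 74.6 FPKM (limma, adjusted p = 1.11e-09). DLK1, a Notch-related membrane protein gene (chromosome 14, 100725705 to 100738224, plus strand), rose from 0.411 ± 0.239 to 13.7 ± 8.31 (adjusted p = 1.86e-05), and CHGA, which codes for the granule protein chromogranin A of endocrine cells, rose from 0.0956 ± 0.110 to 12.8 ± 5.21 (adjusted p = 2.35e-11). FGB, the fibrinogen chain gene, fell from 14.7 ± 1.71 to 1.71 ± 1.57 FPKM, and AC008738.3 opposite CEBPA fell from 2040 ± 106 to 475 ± 71.0 (limma, adjusted p = 3.66e-14). Within PP, DLK1 stood at 6.59, 6.52, 22.2 and 19.5 FPKM in replicates 1 to 4.

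DLK1 was the 1 of 12 called in the pancreatic progenitor list, 1 adjusted over the list alone (camera, adjusted p = 0.00127), and 6 members were higher and 1 lower by the limma adjusted p without the minimum difference. CHGA was the 1 of 7 called in the endocrine list, 1 adjusted over the list alone (camera, adjusted p = 0.000374), with adjusted p = 0.0944 with an estimated correlation. FGB was the 1 of 8 called in the hepatic list, 1 adjusted over the list alone (camera, adjusted p = 0.0224), with adjusted p = 0.0878 with an estimated correlation. The FGB call was lost without PP replicate 2 (-0.98, under the minimum). The ductal list had 0 of 6 called, 0 adjusted over the list alone (camera, adjusted p = 0.0895), with 2 members higher by the limma adjusted p without the minimum difference. The pluripotency list had 0 of 20 called, 0 adjusted over the list alone (camera, adjusted p = 0.0903), with 2 members lower by the limma adjusted p without the minimum difference.

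The largest rises under the naming rule were in LHFPL3 (6.96 ± 3.41 to 337 ± 198 FPKM), LTO1 opposite CCND1, the cyclin D1 gene (9.30 ± 1.72 to 176 ± 144), NPHS1 (3.22 ± 0.484 to 93.0 ± 56.8), RN7SL8P opposite LHFPL3-AS2 (35.5 ± 10.6 to 1220 ± 570) and FAM120A2P opposite WNK2 (39.2 ± 7.35 to 434 ± 19.4). The largest falls were in PRSS23 opposite FZD4, a WNT receptor gene (138 ± 9.23 to 25.9 ± 6.93), KIFC2 opposite FOXH1 (32.7 ± 3.01 to 3.36 ± 0.191), CCDC154 (168 ± 16.5 to 41.0 ± 20.3), ASH2L opposite STAR (38.3 ± 9.31 to 7.47 ± 5.20) and NR2F1-AS1 opposite NR2F1 (37.7 ± 9.59 to 9.29 ± 5.47). With each pair of libraries averaged, the calls of ASH2L and NR2F1-AS1 were lost (limma, adjusted p = 0.0885 and 0.0642). Chosen after their values were seen, AC245884.1 opposite TTYH1 rose from 64.5 ± 6.81 to 1590 ± 664, KRT7-AS opposite the duct keratin gene KRT7 from 6.55 ± 2.25 to 51.4 ± 24.0, and AC020656.1 opposite LYZ, the lysozyme gene, from 87.2 ± 6.91 to 445 ± 117. The last was not called with log2(FPKM + 0.1), with adjusted p = 0.129.

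Of 12325 rows limma called 96, with 75 higher and 21 lower in PP, and 82 of them overlap exons on the other strand. The count was 30 with treat, 596 with log2(FPKM + 1) (316 higher and 280 lower) and 893 with voom (445 higher and 448 lower), and, in fits chosen after the data were seen, 130 with PP replicates 1 and 2 alone and 112 with 3 and 4 alone.

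PP was compared with ESC to give the whole path from stem cells to pancreatic progenitors. In PP, IGF2 had risen from 7.37 ± 0.724 to 3700 ± 869 FPKM (7.91, limma, adjusted p = 2.49e-13), and SOX9 and DLK1 were also higher. Of 20 pluripotency genes 6 fell, with DNMT3B at 0.221 FPKM against 27.3 ± 2.14 in ESC (-2.51, adjusted p = 3.75e-20) and TCF19 opposite POU5F1 at 0.498 against 85.4 ± 6.72. Of 6 tested rows opposite genes of the glycolysis list 3 fell (camera, adjusted p = 0.00931), with adjusted p = 0.127 with an estimated correlation. They were AC006064.4 opposite GAPDH from 120000 ± 8110 to 43100 ± 7150 (-1.58, limma, adjusted p = 7.99e-13), AC005726.4 opposite ALDOC from 2270 ± 215 to 101 and AC093512.1 opposite ALDOA from 649 to 65.8. The fall of AC006064.4 was 0.86 after quantile normalisation, under the minimum.

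In the pluripotency list 6 of 20 fell, 6 adjusted over the list alone (camera, adjusted p = 9.75e-09). Those 6 were DNMT3B, L1TD1, SOX2, PODXL (9.15 ± 1.61 to 1.31 ± 0.262 FPKM), LIN28A and FOXD3. In the gut tube and foregut list 4 of 14 rose, 4 adjusted over the list alone (camera, adjusted p = 0.000722), namely MEIS1, MEIS2, SOX9 and HOXA3. Among pancreatic progenitor genes 3 of 12 rose, 3 adjusted over the list alone (camera, adjusted p = 0.00086), namely DLK1, SOX9 and GATA4, which stood at 12.4, 9.57, 1.05 and 3.12 FPKM in PP replicates 1 to 4. CHGA was the 1 of 7 called in the endocrine list, 1 adjusted over the list alone (camera, adjusted p = 0.0528). In the definitive endoderm list GATA4 was the 1 of 15 called, 1 adjusted over the list alone (camera, adjusted p = 0.919). PKM, a pyruvate kinase gene, was the 1 of 17 called, as a fall, in the glycolysis list, 1 adjusted over the list alone (camera, adjusted p = 0.000144), with adjusted p = 0.0823 with an estimated correlation. Its own row went from 15.4 ± 2.96 to 5.64 ± 0.617 FPKM, and the difference of -1.01 moved under the minimum without ESC replicate 3 (-0.93), without PP replicate 4 (-0.95) and with reference gene scaling (-0.90). MT-CYB, which codes for cytochrome b, was the 1 of 13 mitochondrial transcripts called, as a fall from 1160 ± 123 to 361 ± 73.5, 1 adjusted over the list alone (camera, adjusted p = 0.00137), with adjusted p = 0.402 with an estimated correlation. The Notch and hepatic lists had 0 of 7 and 0 of 8 called, 0 adjusted over the list alone, with camera adjusted p = 0.00435 and 0.00589. For Notch, adjusted p = 0.0944 with an estimated correlation, and without the minimum difference limma found 6 Notch and 8 hepatic members higher.

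Among retinoic acid targets 4 of 17 rose, 5 adjusted over the list alone (camera, adjusted p = 0.00589), with adjusted p = 0.332 with an estimated correlation. In the anterior HOX list 3 of 9 rose, 4 adjusted over the list alone (camera, adjusted p = 0.00822), with adjusted p = 0.509 with an estimated correlation. The 3 were HOXA2, HOXA3 (0.0372 to 9.56 ± 10 FPKM, limma, adjusted p = 0.00732) and HOXB3, and their values parted the PP libraries. In PP replicates 1 to 4, HOXA2 stood at 24.5, 13.8, 0.712 and 0.470 FPKM, HOXA3 at 19.7, 16.7, 0.542 and 1.34, and HOXB3 at 15.7, 10.9, 1.49 and 3.56. The difference of HOXA2 was 0.75 without PP replicate 1 and 0.89 without PP replicate 2, both under the minimum. With PP replicates 3 and 4 alone, a choice made after the data were seen, HOXA2, HOXA3 and HOXB3 differed by 0.33, 0.48 and 0.71, and GATA4 by 0.79. With PP replicates 1 and 2 alone, CHGA differed by 0.97 and MEIS2 by 0.94. With each pair of libraries averaged, the calls of HOXA2, HOXA3 and HOXB3 were lost (limma, adjusted p = 0.178, 0.158 and 0.0863). In a fit of the ESC and PP libraries only, the limma adjusted p was 0.0675 for HOXA2 and 0.0586 for HOXA3.

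**Figure D4:**
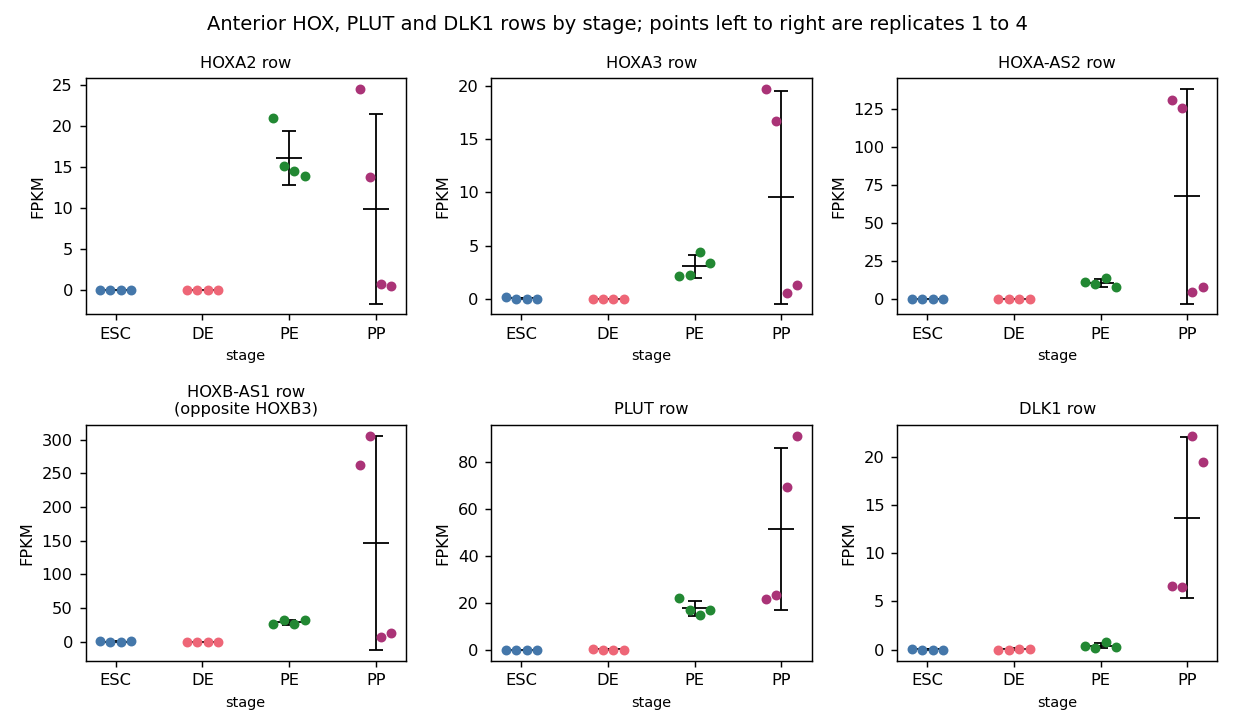
FPKM by stage of 6 rows (HOXA2, HOXA3, HOXA-AS2, HOXB-AS1 opposite HOXB3, PLUT and DLK1), with 1 point per library in the order of replicates 1 to 4 and the mean and SD of 4 libraries. In PP, HOXA2 stands at 24.5, 13.8, 0.712 and 0.470, and DLK1 at 6.59, 6.52, 22.2 and 19.5.

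The largest rises under the naming rule, beside IGF2, included NRAP opposite HABP2 (0.385 to 320 ± 74.2 FPKM), LHFPL3 (0.251 to 337 ± 198) and USP37 opposite VIL1, the gene of the microvillus protein villin (0.697 to 64.3 ± 11.7, limma, adjusted p = 9.43e-22). The largest falls included LARP7 opposite MIR302CHG (2780 ± 422 to 5.93 ± 1.61), GNAS-AS1, THY1-AS1 opposite THY1 (4040 ± 114 to 39.7, adjusted p = 1.42e-22), KIFC2 opposite FOXH1 (365 ± 49.9 to 3.36 ± 0.191, adjusted p = 1.96e-25) and NUDT6 opposite FGF2. KRT8, an epithelial keratin gene whose row lies opposite KRT18, went from 191 ± 7.08 to 477 ± 192 (1.11, adjusted p = 0.00192). Its difference was 0.89 without PP replicate 1 and 0.96 without PP replicate 2.

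Of 12325 rows limma called 777, with 415 higher and 362 lower in PP (53.4% higher). With reference gene scaling, which shifted the median difference by 0.106, 524 were higher and 296 lower (63.9% higher). In the rows without opposite overlap, a choice made after the data were seen, the majority turned to lower, with 55 higher and 69 lower (44.4% higher). The count was 384 with treat, 3104 with log2(FPKM + 1) and 4251 with voom, and, in fits chosen after the data were seen, 766 with PP replicates 1 and 2 alone and 837 with 3 and 4 alone.

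The other lists showed few calls. In their own rows, BMP targets (5 tested), hypoxia (9), cholesterol synthesis (7), proliferation (13) and reference genes (10) had 0 members called in each of the 4 comparisons, 0 adjusted over the list alone. The lowest camera adjusted p was 0.0932 for BMP targets, 0.215 for hypoxia, 0.309 for cholesterol synthesis, 0.0651 for proliferation and 0.4 for reference genes. By the limma adjusted p without the minimum difference, 6 proliferation members were lower and 1 higher in DE against ESC, and 4 BMP targets were higher in PP against ESC. In the epithelial junction list KRT8 was the 1 of 15 called in PP against ESC, 1 adjusted over the list alone (camera, adjusted p = 0.231). In the monogenic diabetes list GATA4 and GATA6 were the 2 of 14 that rose in DE against ESC, 2 adjusted over the list alone (camera, adjusted p = 0.224). SOX9 was the 1 of 6 called in the ductal list in PP against ESC, 1 adjusted over the list alone (camera, adjusted p = 0.101). In lists with under 5 tested members, camera was not run. VIL1, whose row lies opposite USP37, was the 1 of 2 intestinal and gastric members called in DE against ESC, as a fall (-0.99 without ESC replicate 1 and -0.98 with reference gene scaling, both under the minimum). CLDN18, a tight junction gene of the stomach and lung, rose in PP against ESC from 0.324 to 9.14 ± 1.71 FPKM. GABRP, the 1 tested member of the trophoblast and amnion list, fell from 4.64 to 0.125 FPKM in PP against ESC. Of the acinar (2 tested), mesenchyme (2), neural and neural crest (4), endothelial and blood (1), WNT target (4) and Hedgehog (2) lists, 0 members were called. For posterior HOX, 0 of 18 members reached the FPKM minimum.

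Rows that peaked at a stage, higher there than at each other stage, numbered 132 in ESC, 166 in DE, 15 in PE and 46 in PP. Of those with a gene symbol and at least 5 FPKM, the ESC rows with the largest smallest difference to another stage were NUDT6 opposite FGF2, GNAS-AS1, MMP24OS opposite MMP24, JAKMIP2 opposite JAKMIP2-AS1 (36.9 ± 10.1 FPKM) and THY1-AS1 opposite THY1. Those in DE included HAS2-AS1 opposite HAS2, NPAP1 (51.6 ± 6.07), PPP6R3 and the splicing factor gene MBNL2 (39.2 ± 7.35). By the same order, the first in PE were CCDC154, PRSS23 opposite FZD4, ASH2L opposite STAR, NR2F1-AS1 opposite NR2F1 and GLYCTK opposite GLYCTK-AS1 (107 ± 9.54). The first in PP were LHFPL3, RN7SL8P, FAM120A2P opposite WNK2, NPHS1 and NKX2-2-AS1 opposite NKX2-2. Rows named by a clone identifier had larger values in some stages, as Z99774.1 opposite MIAT did in ESC with a smallest difference of 5.65, against 3.71 for NUDT6, and AC008738.3 opposite CEBPA in PE with 1.85, against 1.66 for CCDC154.

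CER1 and LHX1 were among 180 rows called higher in DE than in ESC and again lower in PE than in DE. Independent lists of the same sizes would share 9.66 rows. A simulation with no effect gives no reference here, since limma then called 0 rows. With the DE libraries split, so that the 2 steps shared none, the count was 177 and 172. AC099314.1 opposite CDH1 was among 27 rows that fell and then rose around DE (4.34 for independent lists, 25 and 25 with DE split). FGB and NR2F1-AS1 were among 17 rows that rose into PE and fell into PP (0.42 for independent lists, 17 and 16 with PE split), and 13 fell and then rose around PE (2.37, and 8 and 9 with PE split).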

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

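The tests of the strand on which the counts lie were chosen after that pattern was seen, and the tests of markers' own rows and of other splits of the libraries were set before their results were seen.

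The most far-reaching pattern is that 89.6% of the counts lay in rows that overlap exons of a gene on the other strand, such as AC006064.4 opposite GAPDH. Counting without regard to strand would give a gene and its opposite row similar densities over shared exon. Instead, for 115 coding genes the own row's density had a median of 0.0781% of that of the opposite row, whose whole count was set over the overlap length. Abundant antisense RNA counted on its annotated strand would leave the reference genes' own rows among the highest, but their median percentile among tested rows was 15.4. A stranded library counted with the opposite strand setting was not excluded. It was given no test of its own, because the 89.6% is the pattern itself. Such counting would also raise MT-ND6 above the heavy-strand genes, and MT-ND6 stood at 41800 FPKM against their median of 791 FPKM. That value goes with this explanation but was seen before the explanation was written down. For the 115 genes, the densities argue against counting without regard to strand. For the reference genes, the percentile argues against abundant antisense RNA counted on its annotated strand. Of the explanations weighed here, only the opposite strand setting remains. The counting step was not seen, so that setting was not checked directly, and no biological explanation beyond antisense RNA was tested.

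A linked pattern is that the own rows of stage markers such as SOX17, CER1 and PDX1 changed between stages despite low counts. A small fixed share of each gene's own mRNA reads counted in its own row would give similar density ratios across the 115 genes, but the upper quartile was 6.51 times the lower. A share that differs between genes stays open. The ratio also varies with how much of the opposite row's count lies outside the overlap, so this test does not settle the question. Antisense RNA made independently of the gene would leave the own and opposite rows' changes unrelated, but across genes, which are not independent replicates, Pearson's r was 0.456 in PE against DE (Spearman 0.532) and 0.741 in DE against ESC (Spearman 0.674). Antisense RNA regulated together with its gene would give such an r too, so residual reads and antisense RNA cannot be told apart here, and which of them the SOX17 and PDX1 values reflect may differ from gene to gene.

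Of the 35 ways to split the 8 libraries of a comparison only 1, the real one, gave as many calls. Each other split mixes the stages, which puts the stage difference into the spread, so few calls were bound to follow. The test therefore shows only that the calls depend on the stage labels. It cannot exclude chance differences between cultures, for instance if libraries 1 and 2, and 3 and 4, of a stage came from the same culture. The real count was 521 in DE against ESC, 638 in PE against DE, 96 in PP against PE and 777 in PP against ESC, and the highest of the other splits was 0 in each.

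Single libraries stood apart from the other 3 of their stage, by the gap over the range, in 15 of 306 groups of 4 values, where chance alone gives 15.3. The total does not show how these were spread, and DE replicate 3 held more of them than any other library. Its score on the second principal component was 23.45, with 26.98 to 28.45 for the other DE libraries. Without it, 552 rows were called in DE against ESC, and 521 with all libraries. In DE replicate 3, FOXA2 was at 0.711 FPKM (others 1.83 to 2.02), TLDC2 at 4.35 (0.8 to 1.29), AC078860.1 opposite LGR5 at 286 (231 to 238), AC099314.1 opposite CDH1 at 781 (620 to 647) and PPP6R3 at 59.0 (64.2 to 64.8). In PE replicate 3, AC243773.1 opposite LHX1 was at 18 (30.2 to 31.6) and NRAP opposite HABP2 at 333 (290 to 296), and in PE replicate 4 SLC46A1 was at 288 (276 to 278). In PP, M6PR opposite PHC1 was at 30.3 in replicate 3 (33.5 to 33.6), PKM at 4.71 in replicate 4 (5.89 to 5.99) and AC126696.2 opposite SLC7A5 at 225 in replicate 1 (131 to 143). PKM was at 24.6 in DE replicate 4 (others from 19.9), GABRP at 5.28 in ESC replicate 1 (4.34 to 4.49) and CLDN18 at 1.05 in DE replicate 1 (2.7 to 2.88). The total count of PE replicate 1 was 1644743 (others 1729495 to 1745939).

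Of the rows left out for lack of an FPKM value, the one with the most counts held 122160 over the 16 libraries, with 7571 to 7923 per ESC library, 4592 to 5143 in DE, 9868 to 10825 in PE and 7175 to 8295 in PP. It had no match in GENCODE release 29, so what it measures is not known here.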

How the results depend on the processing

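Voom, the choice of rows by overlap, the PP pairs, the batch term, the averaged pairs and the lists read through opposite rows were chosen after the data were seen. In the order DE against ESC, PE against DE, PP against PE and PP against ESC, limma called 521, 638, 96 and 777 rows. The counts were 2260, 2699, 596 and 3104 with log2(FPKM + 1), 2940, 3465, 692 and 4031 with log2(FPKM + 0.1), and 3071, 3675, 893 and 4251 with voom. The VST compresses differences at low counts, so a fixed minimum of 1 asks more there than on these scales. Without the minimum difference the counts were 4868, 5216, 1608 and 6034, with treat 269, 341, 30 and 384, and in rows without opposite overlap, where fewer rows were tested, 114, 147, 14 and 124. Leaving out each library gave 504 to 552, 616 to 658, 90 to 104 and 779 to 810. Filters, other scalings, the batch term, no trend and only the stages compared kept each count within 1.5 times, and 0 called rows turned direction under any setting. The share higher in PE against DE was 39.0%, against 56.1% with log2(FPKM + 1), 58.1% with log2(FPKM + 0.1) and 57.6% with voom, and in PP against PE 78.1%, against 53.0%, 49.9% and 49.8%. The cause was not tested. With libraries 1 and 2, and 3 and 4, of each stage averaged, the counts were 516, 623, 80 and 757. The replicate block gave 521, 636, 95 and 777 calls. Libraries sharing a replicate number correlated at -0.076 to 0.191, with 2 of 24 above 0.1 and 9 of 24 best with their own number. For replicate 4, ESC with DE, ESC with PE and DE with PE gave 0.1, 0.191 and 0.179, each best with its own number. The stage-peaking genes numbered 1398 with log2(FPKM + 1), 1523 with log2(FPKM + 0.1), 1841 with voom and 95 without opposite overlap. Of the 96 tests of a list in a comparison, 29 were called with camera, 16 with the correlation estimated and 62 with fry, which asks a different question. Through opposite rows, where fewer lists could be tested, 18 such tests were called. With log2(FPKM + 1) and log2(FPKM + 0.1), rows with a rise then fall, peak at DE, numbered 609 and 675, those with a fall then rise, trough at DE, 223 and 406, those with a peak at PE 166 and 161, and those with a trough at PE 67 and 100. Over named genes and settings 5462 values stayed on their side of the threshold, 145 lost their call, 92 gained one and 0 reversed. Markers that gained a call, such as PDX1, NKX6-1 and FOXA2, did so mainly on the FPKM scales, with voom or without the minimum. Depth limits what the low rows show, as NKX6-1 in PP rested on 10 to 42 counts per library and INS on none. The strand pattern limits them too, since even the reference genes' own rows had a median of 0.769 FPKM. A low or empty own row, as for INS, therefore does not show that the gene was silent.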

Other observations

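The lists read through opposite rows, the PP values and the rows named by a clone identifier were chosen after the data were seen. Reading a list through the row opposite each member gave fewer testable members, and each count of calls below was the same adjusted over the list alone. In the gut tube and foregut list, 6 of 6 such rows rose in PE against DE (camera, adjusted p = 7.32e-09, and adjusted p = 0.00111 with an estimated correlation), among them those opposite the apolipoprotein gene APOA1, the cadherin gene CDH6, and the transcription factor genes MEIS1, MEIS2 and PROX1, and 6 of 6 were higher in PP than in ESC (adjusted p = 1.34e-07). In the pancreatic progenitor list 4 of 5 rose in PP against ESC (camera, adjusted p = 0.000146, and adjusted p = 0.00769 with an estimated correlation), those opposite GATA6, NKX2-2, PROX1 and GLIS3. GLIS3-AS1 opposite GLIS3, a beta cell transcription factor gene, stood at 5.34 ± 1.66 FPKM in PE and 43.4 ± 13.0 in PP. In the pluripotency list 5 of 5 fell in PP against ESC (camera, adjusted p = 2.96e-08, and adjusted p = 0.00195 with an estimated correlation), those opposite FOXH1, FGF2, POU5F1, FOXD3 and TDGF1. The rows opposite 4 definitive endoderm genes rose in DE and fell in PE, 4 of 4 at each step, too few for a list test.

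Among other lists read this way, 3 of 6 glycolysis rows fell in PP against ESC (camera, adjusted p = 0.00931), those opposite GAPDH, ALDOA and ALDOC, with adjusted p = 0.127 with an estimated correlation. In the epithelial junction list 2 of 5 rose in PE against DE (camera, adjusted p = 0.00131), with adjusted p = 0.0697 with an estimated correlation. In the monogenic diabetes list 4 of 7 rose and 1 fell in PP against ESC (camera, adjusted p = 0.0114), with adjusted p = 0.0644 with an estimated correlation. In the cholesterol synthesis list 2 of 5 fell in PE against DE (camera, adjusted p = 0.0267), with adjusted p = 0.327 with an estimated correlation. In PP against PE 1 of 5 rose (camera, adjusted p = 0.000146), with adjusted p = 0.127 with an estimated correlation, and 5 were higher by the limma adjusted p without the minimum difference. That row, AC114947.2 opposite HMGCS1, lost its call with each pair of libraries averaged (limma, adjusted p = 0.262). It was also among those that fell in PE against DE, where log2(FPKM + 1) and voom each gave -0.94, under the minimum.

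Within PP the libraries parted in the same way in several rows, given here for replicates 1 to 4. HOXB-AS1 opposite HOXB3 stood at 262, 306, 6.74 and 13.3 FPKM, HOXA-AS2 at 131, 126, 5.19 and 8.42, HOXB-AS3 at 106, 101, 0.305 and 6.94, and HOTAIRM1 at 56.0, 45.9, 0.390 and 3.09. PDE11A-AS1 stood at 252, 250, 17.3 and 10.9 and CADM3-AS1 at 141, 107, 13.3 and 30.4. PLUT, an RNA gene next to PDX1, went the other way, at 21.8, 23.5, 69.5 and 91.4, as did NPHS1 at 46.9, 53.5, 102 and 170, and LTO1 opposite CCND1 stood at 72.7, 94.0, 386 and 151. In PE, HOXB-AS1 ranged from 25.9 to 33.0 FPKM over the 4 libraries and PLUT from 14.8 to 22.2. The labels name no batch, and no explanation of this split was tested.

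The IGF2 row stood apart from the strand pattern, at 3700 ± 869 FPKM in PP in its own row, while IGF2-AS, which overlaps 333 bp of its exons on the other strand, stood at 49.6 FPKM. The reason was not tested. KIFC2 and FOXH1 overlap each other, and in PP the KIFC2 row was at 3.36 ± 0.191 FPKM and the FOXH1 row at 49.4, against 365 ± 49.9 and 89.2 ± 12.6 in ESC.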
